A study of Mus musculus with 12 samples.

How the data were processed

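RNA sequencing of total liver RNA was deposited for 12 mouse liver samples. Per the labels, RNA was isolated with a silica-column kit (RNeasy Plus Mini), libraries were made with TruSeq RNA kits and read on an Illumina HiSeq instrument. Per the submitters' processing notes, transcript abundance was estimated with kallisto, a pseudoalignment program, against mm10, and the deposited values are TPM (relative transcript levels) per gene symbol. The notes give no kallisto version and no annotation release. Checked on the values, no entry lay below 1, 17258 of 31253 symbols stood at 1 in all 12 libraries, 9770 stood above 1 in all, and totals exceeded 1000000 by 16116 to 18237. The notes mention no floor, but the values were read as having one at 1, so that a value of 1 means 1 or less and a fold against a group at 1 is a lower bound on the log2(TPM + 1) scale. TPM keeps no depth, so the depth per sample and the counting precision it gives are unknown. No 2 of the 66 library pairs were identical, and 25 symbols were date-like, as a spreadsheet writes them.

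Samples were grouped by genotype and treatment as the labels give them, with 3 libraries in each of 4 groups. The labels do not say that each library is a separate animal, so the p-values measure only the spread between these samples. For the time of collection, 1 label field gives 33 to 41 weeks and another 30 to 38 weeks. The second was read as counted from treatment at 3 weeks of age, on which reading the fields agree. The age of each single library is not given. Genes were kept when their TPM exceeded 1 in at least 3 of the 12 libraries, which left 12120. The planned filter, a TPM of at least 1 in 3 libraries, removes nothing from values with a floor of 1 and was read as above 1.

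Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1, in 1 linear model of the 4 groups with empirical Bayes moderation and a mean-variance trend, which left 8 residual degrees of freedom. The 7 contrasts were DEN in wild type, DEN in S302A, S302A in untreated livers, S302A after DEN, their interaction, the average DEN effect and the average S302A effect. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the lists of a contrast. Near-identical paralogs (Mup, Cyp2c, Cyp4a, Saa, Ces1 and Cyp2a genes) share sequence, so their single values are uncertain. The overlap of DEN calls was tested with Fisher's exact test.

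There were 35 lists fixed beforehand from textbook knowledge, and the 29 with at least 5 measured genes were tested: study genes, fatty acid and triglyceride synthesis, lipid droplet, cholesterol synthesis, fatty acid oxidation, bile acid, xenobiotic metabolism, male-biased and female-biased genes, cell cycle, liver tumour and fetal liver, stem and progenitor, p53 targets, NRF2 targets, unfolded protein response, acute phase, interferon response, gluconeogenesis, circadian clock, pericentral and periportal hepatocyte, proteasome, ribosomal proteins, and the markers of hepatocytes, cholangiocytes, macrophages, lymphocytes, stellate cells and sinusoidal endothelium. Neutrophil, erythroid, adipocyte, exocrine pancreas, striated muscle and mitochondrial lists had fewer than 5 measured genes and were not tested. Under an older symbol 5 members were found, and 10 were not found. Lists can share members, so their results are not independent. Cyp4a10 and Cyp4a14 were in the fatty acid oxidation and female-biased lists, and Cyp2c37 was in the xenobiotic and pericentral lists. Gsta1, Gsta2, Gstm1 and Gstm3 were in the NRF2 and xenobiotic lists.

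Named genes followed a rule: in each contrast the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose mean was at least 5 TPM in the higher group, then Celf1, Psmd10, Cebpa, Cebpb, Hnf4a, Nr1h4, Trp53 and Rb1, then up to 4 members of each list with the smallest p. By chance alone 10% of genes have non-overlapping groups with 3 libraries against 3. The groups, contrasts, lists, naming rule, threshold and most alternatives were chosen before the data were examined. A repeat of the naming rule without S302A_DEN replicate 3, the mitochondrial gene names left out with the most abundant genes, and the genes drawn by group were chosen after the data were seen. Some genes that this rule selects are not reported here.

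Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of TPM at least 5 in 3 libraries, median-of-ratios scaling, quantile normalization, array quality weights, the libraries of a contrast alone, robust moderation, a replicate block, leaving out the most abundant genes and leaving out each library in turn. The planned fit of array weights by restricted maximum likelihood did not converge, and gene-by-gene estimation was used, which gave S302A_DEN replicate 3 a weight of 0.0498 and the others 0.431 to 3.45. Where leaving out a library left 2 in a group, the spread was pooled over the groups. The model was tested on simulated data with the spread of these libraries and 100 changed genes per fold. It recovered 28% to 35% of 2-fold and 88% to 89% of 4-fold changes in the 4 pairwise contrasts and 2% and 57% in the interaction, with 0 wrong signs, and called 2 to 13 unchanged genes. Changes were placed only in genes with a mean log2 level above that of 5 TPM. Errors were drawn independently, with 1 spread per gene for all libraries. These rates therefore do not cover lower genes or an outlying library. Gene positions and the Celf1 codon came from the mm10 annotation. Reads, splicing and protein were not analysed here.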

Results

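Messenger RNA levels were measured by RNA sequencing in 12 liver libraries from male C57BL6 mice. The mice were wild type (WT) or carried the S302A knock-in, an engineered allele that replaces a serine of the RNA-binding protein CUGBP1, encoded by Celf1, with alanine. Some mice of each genotype had received diethylnitrosamine (DEN), a DNA-alkylating liver carcinogen, at 50 µg per g body weight and 3 weeks of age, and livers were collected 30 to 38 weeks later. The 4 groups were untreated wild type (WT_Ctrl), DEN-treated wild type (WT_DEN), untreated knock-in (S302A_Ctrl) and DEN-treated knock-in (S302A_DEN), with n = 3 libraries each. Values were TPM, a relative transcript measure that divides out library size, so the sequencing depth behind each value is unknown. Each library listed 31253 gene symbols with no value below 1, and 58.1% to 65.3% of the symbols stood at exactly 1.

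S302A_DEN replicate 3 stood apart from the other 11 libraries. Its Spearman correlations with them across genes were 0.877 to 0.913, against 0.937 to 0.980 for the 55 pairs without it. It listed 13083 genes above 1 TPM, against 10839 to 11653 in the others. Its 20 most abundant genes held 23.8% of its TPM, against 35.9% to 47.6%. In this library Ly6d, a surface antigen found on precancerous and cancerous hepatocytes, reached 422 TPM, against 2.30 and 1.90 in the other S302A_DEN replicates. Gpc3, a fetal glypican re-expressed in liver tumours, reached 51.4 TPM, against 1.28 and 1. The antioxidant enzyme gene Nqo1 reached 239 TPM, against 2.34 and 1.79, and the cytochrome Cyp2a5 reached 15026 TPM, against 62.0 and 80.6. Most genes stood higher in this library: 10539 of 12120 (87.0%) lay above both other S302A_DEN replicates and 631 below both, with a median log2 difference of 0.79, and its median-of-ratios factor was 1.69, against 0.820 to 1.18 in the others. Above both lay 34 of 34 proteasome genes (median 0.58), 76 of 78 ribosomal protein genes (1.02), 19 of 19 p53 targets (1.28), 14 of 14 stellate cell genes (1.51) and 17 of 17 cell cycle genes (1.85). All 16 measured targets of NRF2, the oxidative stress transcription factor, lay above both other S302A_DEN replicates, with a median log2 difference of 3.56. So did 10 of 12 liver tumour and fetal liver genes (3.52), 21 of 21 interferon response genes (2.34) and 13 of 14 macrophage genes (2.09). Of 25 male-biased liver genes, 19 lay below both (median -1.91), among them the major urinary protein gene Mup1 at 168 TPM, against 4278 and 5153.

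**Figure D1:**
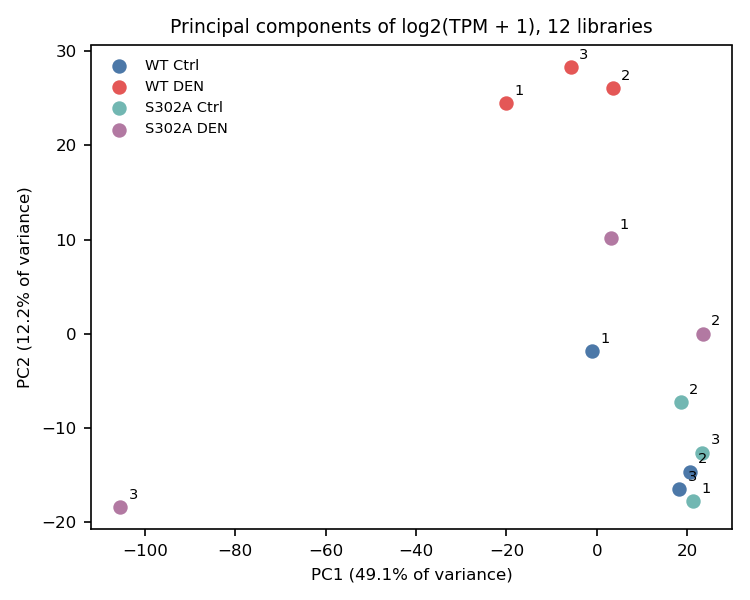
Principal components 1 and 2 of log2(TPM + 1), with 1 point per library coloured by group; the axes give component scores, and the components held 49.1% and 12.2% of the variance. S302A_DEN replicate 3 lies far from the other 11 libraries on component 1.

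The series concerns degradation of CUGBP1 by gankyrin, a proteasome-associated oncoprotein encoded by Psmd10, in fatty liver and liver cancer. Celf1 lies on mm10 chromosome 2 from 90940382 to 91019497 on the plus strand. The codon at the position in the allele's name is AGC (serine) in its 486-residue isoforms, at 91009216 to 91009218 in exon 10 of 14 of Celf1-203. It is also serine in the 483-residue isoform, but glutamine or proline in the 513-residue and 487-residue isoforms, and the labels do not say which isoform is numbered. A changed codon does not show in TPM, so Celf1 levels do not check the genotype labels. Celf1 stood at 13.3, 9.35 and 12.7 TPM in WT_Ctrl replicates 1 to 3 and at 13.5, 12.6 and 11.4 in WT_DEN. It stood at 18.1, 18.4 and 13.2 TPM in S302A_Ctrl and at 20.6, 18.97 and 23.8 in S302A_DEN. The knock-in mean exceeded the wild-type mean by 0.46 on the log2 scale without DEN (limma adjusted p = 1) and by 0.71 after DEN (adjusted p = 0.242), so neither difference passed the test. Psmd10 averaged 7.81 ± 0.996 TPM (SD, n = 3) in WT_Ctrl, 8.11 ± 2.12 in WT_DEN, 6.38 ± 0.729 in S302A_Ctrl and 13.7 ± 9.50 in S302A_DEN. S302A_DEN replicate 3 held 24.6 TPM of Psmd10, against 8.65 and 7.71 in the other S302A_DEN replicates, and no Psmd10 difference passed the test. The same held for 6 further genes of hepatocyte identity and tumour suppression: Cebpa, Cebpb and Hnf4a, which encode liver transcription factors, Nr1h4, which encodes the bile acid receptor, and Trp53 and Rb1. Hnf4a averaged 116 ± 7.45, 159 ± 16.5, 116 ± 9.40 and 170 ± 19.6 TPM in WT_Ctrl, WT_DEN, S302A_Ctrl and S302A_DEN (SD, n = 3), and its DEN differences were 0.46 (adjusted p = 0.460) and 0.55 (adjusted p = 0.154).

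**Figure D2:**
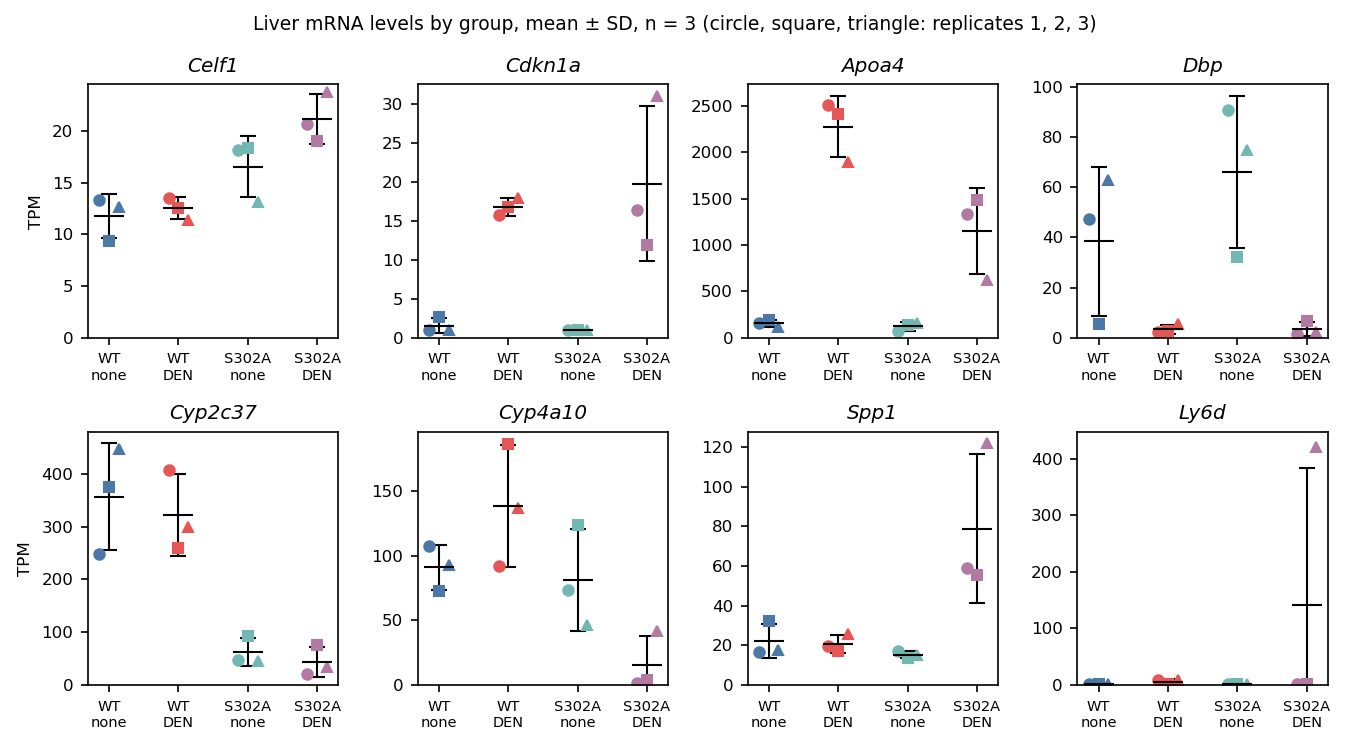
Levels of 8 genes in the 4 groups in TPM on a linear axis from 0; dashes give the mean, whiskers the SD (n = 3) and points the libraries. Celf1 lies between 9.35 and 23.8 TPM in all 12 libraries, and Ly6d reaches 422 TPM in S302A_DEN replicate 3 alone.

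The comparison of WT_DEN with WT_Ctrl asked what DEN left behind in wild-type liver. Apoa4, an apolipoprotein of triglyceride-rich particles on chromosome 9 (46240696 to 46243459, plus strand), rose from 155 ± 40.4 to 2277 ± 329 TPM (SD, n = 3). Its log2 change was 3.89 ± 0.38 (SE; adjusted p = 0.00219). Cdkn1a, the p53-induced cell cycle inhibitor p21 on chromosome 17 (29090976 to 29100727, plus strand), rose from 1.55 ± 0.957 to 16.8 ± 1.14 TPM (log2 change 2.86 ± 0.33, adjusted p = 0.00693). Nfil3, a transcription factor of the circadian system, rose 3.90-fold in TPM, from 9.49 ± 2.57 to 37.0 ± 4.22. Epha2, a receptor tyrosine kinase, and Zbtb16, a zinc-finger transcription factor, rose 4.37-fold and 4.56-fold. Acot3, a peroxisomal acyl-CoA thioesterase, rose from 1.502 ± 0.746 to 13.7 ± 7.18 TPM, and the dynein light chain gene Dynlt1b rose from 3.87 ± 2.51 to 32.3 ± 5.14 TPM. In total 16 of 12120 tested genes passed limma at an adjusted p below 0.05, 14 up and 2 down, and 1001 had an unadjusted p below 0.05. With the libraries of this contrast alone 147 of 11464 genes passed, 121 up and 26 down, all 16 included. The median log2 change of all tested genes was 0.13, which median-of-ratios scaling brought to -0.02, with 11 genes up and 8 down. The count was 9 without WT_Ctrl replicate 1, 6 without WT_Ctrl replicate 2, 8 without WT_DEN replicate 2, 1 without WT_DEN replicate 3, 9 without S302A_Ctrl replicate 3 and 258 without S302A_DEN replicate 3, an alternative with 229 up and 29 down singled out after the data were seen. The Apoa4 call held under each left-out library, and the Cdkn1a call ended without WT_DEN replicate 3 (adjusted p = 0.0660). Each call of Nfil3, Epha2, Zbtb16, Acot3 and Dynlt1b ended on leaving out 1 or more of all WT_Ctrl and WT_DEN replicates, S302A_Ctrl replicate 3 and S302A_DEN replicate 1, at adjusted p from 0.0505 to 0.247, and the Acot3, Epha2 and Zbtb16 calls ended under median-of-ratios scaling (0.0517, 0.0617 and 0.0759). With a replicate block 5 genes passed, 3 up and 2 down. Apoa4 and Cdkn1a were among them, so most of the other calls named here ended. Without a filter 3 genes passed, and the calls of Dynlt1b and Nfil3 (0.0660 each), Acot3 and Epha2 (0.0848 each) and Zbtb16 (0.0526) ended. So did those of Epha2 and Zbtb16 with quantile normalization (0.0672 and 0.0886), and those of Dynlt1b (0.0561), Acot3 (0.0646), Epha2 and Zbtb16 (0.0791 each) without the most abundant genes.

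Genes of fatty acid and triglyceride synthesis stood higher after DEN in wild type. All 21 measured members were higher, with a median log2 change of 0.97 (0.79 after median-of-ratios scaling; camera adjusted p = 7.01e-10), and this call was lost at adjusted p = 0.849 with an estimated correlation. None passed limma over all genes, while 11 passed upward adjusted over the list alone. Dgat2, which makes triglyceride, averaged 143 ± 20.4 TPM in WT_Ctrl and 261 ± 30.9 in WT_DEN (SD, n = 3; adjusted p = 0.128). Fads2, a fatty acid desaturase, averaged 102 ± 19.3 and 199 ± 13.7 TPM (adjusted p = 0.211). Of 20 fatty acid oxidation genes, 19 were higher (median 0.46, camera adjusted p = 0.00208), lost at adjusted p = 0.990 with an estimated correlation; 0 passed limma over all genes and 0 adjusted over the list alone. Among female-biased liver genes, which male growth hormone pulses hold low, 14 of 15 were higher (median 0.62, camera adjusted p = 0.00122), lost at adjusted p = 0.849 with an estimated correlation; 1, Acot3, passed over all genes and 4 adjusted over the list alone. Male-biased genes stood lower, 15 of 25 (median -0.43, camera adjusted p = 4.71e-05), lost at adjusted p = 0.990 with an estimated correlation and at 0.0983 under median-of-ratios scaling; 0 passed either adjustment, and the median was -0.10 without WT_Ctrl replicate 2. Mup1 averaged 4908 ± 1407 TPM in WT_Ctrl and 1064 ± 583 in WT_DEN (adjusted p = 0.543, and 0.0258 without S302A_DEN replicate 3). Of 19 p53 targets 17 were higher (median 0.29, camera adjusted p = 0.0484), lost at adjusted p = 0.990 with an estimated correlation and without WT_Ctrl replicate 1 (0.228), WT_Ctrl replicate 3 (0.0522), WT_DEN replicate 2 (0.0569) or WT_DEN replicate 3 (0.0519). Of them 1 passed over all genes and 1 adjusted over the list alone. Hepatocyte genes stood higher in 14 of 15 (median 0.36, camera adjusted p = 0.00744), lost at adjusted p = 0.990 with an estimated correlation, at 0.0519 without WT_DEN replicate 3 and at 0.192 under median-of-ratios scaling. The median was 0.23 without WT_Ctrl replicate 2, and 0 passed over all genes and 3 adjusted over the list alone. Sinusoidal endothelial genes were higher in 13 of 13 (median 0.44, camera adjusted p = 0.0275), lost at adjusted p = 0.990 with an estimated correlation, without WT_Ctrl replicate 1 (0.696, median 0.27), WT_DEN replicate 3 (0.136) or S302A_DEN replicate 3 (0.121), and under median-of-ratios scaling (0.0574). These 7 of 29 lists passed camera. The libraries of this contrast were also split 3 against 3 in all 10 ways. Of these splits, the real one included, 8 gave at least 7 lists, and the highest other gave 14. The number of lists therefore does not set DEN apart from a regrouping of the samples. Lipid droplet genes were higher in 13 of 16 without passing (median 0.28, camera adjusted p = 0.0581), as were cholesterol synthesis genes (0.48, adjusted p = 0.173).

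In the knock-in, the comparison of S302A_DEN with S302A_Ctrl asked the same question. Cdkn1a stood at 1 TPM in all S302A_Ctrl libraries and rose to 19.8 ± 9.97 TPM (SD, n = 3), with a log2 change of 3.27 ± 0.33 (SE; adjusted p = 0.00159). Apoa4 rose from 123 ± 49.4 to 1148 ± 464 TPM (3.21 ± 0.38, adjusted p = 0.00199). Spp1, the secreted matrix protein osteopontin on chromosome 5 (104435118 to 104441050, plus strand), rose from 15.3 ± 1.70 to 78.8 ± 37.6 TPM (2.20, adjusted p = 0.0125), with 122 TPM in S302A_DEN replicate 3 and 59.0 and 55.3 in the others. Tff3, a secreted mucosal peptide, rose from the floor of 1 to 116 ± 129 TPM, with 264 in S302A_DEN replicate 3. Sqle, an enzyme of cholesterol synthesis, rose from 10.4 ± 6.91 to 60.4 ± 32.6 TPM. Dbp, a clock-output transcription factor on chromosome 7 (45705088 to 45710203, plus strand), fell from 66.0 ± 30.2 to 3.57 ± 2.82 TPM (-3.92, adjusted p = 0.0398). Inmt, a methyltransferase, fell from 558 ± 43.9 to 125 ± 48.2 TPM, and Cyp2b10, a drug-metabolising cytochrome P450, fell from 7.73 ± 1.73 to 1.44 ± 0.769 TPM (-1.86, adjusted p = 0.0127). Rpph1, the RNase P RNA, fell from 17.0 ± 8.86 TPM to the floor of 1 (adjusted p = 0.00180), and the 45S ribosomal precursor Rn45s fell from 2087 ± 814 to 316 ± 38.5 TPM. In total 75 genes passed, 51 up and 24 down, and 1985 had an unadjusted p below 0.05. The median log2 change of all genes was 0.27, which median-of-ratios scaling brought to 0.01, with 306 up and 345 down. The count was 289 (145 up, 144 down, 70 of the 75 included) without S302A_DEN replicate 3. Without S302A_DEN replicate 2 it was 335 (300 up, 35 down). It was 46, 31 and 47 without WT_Ctrl replicate 1, WT_DEN replicate 2 and WT_DEN replicate 3, and 16, 29 and 20 without S302A_Ctrl replicates 1, 2 and 3; without WT_Ctrl replicate 3 it was 50. The Cdkn1a, Apoa4 and Rpph1 calls held under each left-out library. The Spp1 call ended without S302A_Ctrl replicate 3 (adjusted p = 0.0564), the Rn45s call without S302A_Ctrl replicate 1 (0.0568) and the Cyp2b10 call without S302A_Ctrl replicates 2 and 3 (0.0544 and 0.0638). With the libraries of this contrast alone 17 genes passed, and the Spp1 (0.0554), Cyp2b10 (0.0998) and Sqle (0.137) calls ended. In wild type that setting gave 147 genes in place of 16, so the counts do not rank the DEN responses of the genotypes. Without a filter the Inmt (0.0549), Tff3 (0.0610), Dbp (0.0848) and Sqle (0.0861) calls ended, and with robust moderation the Dbp call did (0.0578). The Tff3, Inmt, Sqle and Dbp calls ended on leaving out various ones of S302A_Ctrl replicates 1 to 3, WT_Ctrl replicates 1 and 2, WT_DEN replicates 1 to 3, S302A_DEN replicate 1 and, for Sqle, S302A_DEN replicate 3, at adjusted p from 0.0501 to 0.205.

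Genes of the unfolded protein response, which restores folding in the endoplasmic reticulum, stood higher after DEN in the knock-in. Of 18 measured genes 17 were higher (median 0.96, 0.67 after median-of-ratios scaling; camera adjusted p = 1.92e-07), lost at adjusted p = 0.254 with an estimated correlation. Over all genes 3 passed upward, and 11 did adjusted over the list alone. The chaperone gene Hspa5 rose from 244 ± 78.1 to 668 ± 24.7 TPM (SD, n = 3; adjusted p = 0.0421), Manf from 31.3 ± 15.3 to 107 ± 5.08 (0.0319) and Creld2 from 16.6 ± 6.40 to 74.9 ± 21.9 (0.0432). These 3 calls ended without 1 or more of WT_Ctrl replicates 1 and 2, WT_DEN replicates 2 and 3, S302A_Ctrl replicates 1 to 3 and S302A_DEN replicates 1 and 2 (adjusted p from 0.0505 to 0.205), and Hspa5 and Creld2 also under median-of-ratios scaling (0.0603 and 0.0621). Hspa5, Manf and Creld2 also lost their calls without a filter (0.0726, 0.0672 and 0.0859) and with the libraries of this contrast alone (0.112, 0.112 and 0.0643), and Creld2 with quantile normalization (0.0633). Cholesterol synthesis genes were higher in 23 of 24 (median 0.96, camera adjusted p = 0.000307), lost at adjusted p = 0.693 with an estimated correlation; 1 passed over all genes and 11 adjusted over the list alone, and 21 of 24 lay above both other replicates in S302A_DEN replicate 3. Acute phase genes, the liver's secreted inflammatory proteins, were higher in 25 of 26 (median 0.64, camera adjusted p = 0.000307), lost at adjusted p = 0.270 with an estimated correlation and at 0.289 without S302A_DEN replicate 2. Of them 1, Saa3, passed over all genes (0.0887 without S302A_Ctrl replicate 1 and 0.112 with the libraries of this contrast alone) and 9 adjusted over the list alone. The interferon response was higher in 21 of 21 genes (median 1.09, camera adjusted p = 0.000307), lost at adjusted p = 0.693 with an estimated correlation; 0 passed over all genes and 5 adjusted over the list alone. All 21 stood highest in S302A_DEN replicate 3, without which the interferon median was 0.29; it was 1.67 without S302A_DEN replicate 2. Clock genes were lower in 12 of 18 (median -0.67, camera adjusted p = 3.11e-07), lost at adjusted p = 0.250 with an estimated correlation; Nfil3 rose and Dbp fell over all genes, 2 rose and 7 fell adjusted over the list alone, and the median was -0.37 without S302A_Ctrl replicate 1. The Nfil3 call held in 14 of 23 alternative settings. Among others it ended without a filter (0.0592) and with the libraries of this contrast alone (0.177). It also ended without WT_Ctrl replicate 1, WT_DEN replicates 2 and 3, S302A_Ctrl replicates 1 and 3 or S302A_DEN replicate 1 (0.0512 to 0.183). Fatty acid oxidation genes were lower in 17 of 20 (median -0.13, mean -0.50, camera adjusted p = 1.43e-08), lost at adjusted p = 0.413 with an estimated correlation. None of them passed over all genes and 3 fell adjusted over the list alone; without S302A_DEN replicate 3, where 18 of 20 lay above both other replicates, these counts were 6 and 14 and the median was -0.46. That median was -0.08 without S302A_Ctrl replicate 2 and -0.02 without S302A_DEN replicate 2. Ribosomal protein genes were higher in 76 of 78 (median 0.56, 0.25 after median-of-ratios scaling; camera adjusted p = 3.11e-07), lost at adjusted p = 0.726 with an estimated correlation; 76 of 78 lay above both other replicates in S302A_DEN replicate 3, and the median was 0.21 without it.

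A further 10 of the 29 lists passed camera after DEN in the knock-in, which made 17. Of the 10 splits of these libraries, the real one included, 3 gave at least 17 lists (highest other 18). The xenobiotic metabolism list, cytochromes P450 and their regulators, had a median of 0.18, a mean of -0.01 and a downward camera call (adjusted p = 9.83e-06), lost at adjusted p = 0.383 with an estimated correlation; its median was -0.13 under median-of-ratios scaling and -0.59 without S302A_DEN replicate 3. It was 0.32, 0.08, 0.29 and 0.40 without S302A_Ctrl replicates 1 and 2 and S302A_DEN replicates 1 and 2. Cyp2b10 and Cyp3a25 fell within it over all genes, and 4 fell adjusted over the list alone. The Cyp3a25 call ended without S302A_Ctrl replicates 1, 2 and 3 (0.0966, 0.0742 and 0.0570) and with the libraries of this contrast alone (0.148). Periportal hepatocyte genes were lower in 10 of 15 (median -0.36, camera adjusted p = 6.13e-05), lost at adjusted p = 0.250 with an estimated correlation and at 0.221 (median -0.17) without S302A_DEN replicate 3, where 9 of 15 lay below both others; the median was -0.24 without S302A_Ctrl replicate 3. Cholangiocyte genes, markers of bile duct cells, were higher in 4 of 5 (median 0.71, camera adjusted p = 0.0356), lost at adjusted p = 0.616 with an estimated correlation and at 0.0624 without S302A_Ctrl replicate 2; the median was 0.41 without S302A_DEN replicate 3. The p53 targets were higher in 18 of 19 (median 0.52, camera adjusted p = 0.0240), lost at adjusted p = 0.747 with an estimated correlation, without S302A_Ctrl replicate 1 (0.0798) and without S302A_DEN replicate 3 (0.298, median 0.07); the median was 0.82 without S302A_DEN replicate 2. Proteasome subunit genes were higher in 34 of 34 (median 0.34, camera adjusted p = 0.0161), lost at adjusted p = 0.747 with an estimated correlation, at 0.113 without S302A_DEN replicate 1 and at 0.336 under median-of-ratios scaling (median 0.03); the median was 0.53 and 0.14 without S302A_DEN replicates 2 and 3. The bile acid (median 0.01), gluconeogenesis (0.12), hepatocyte (0.02), male-biased (-0.25) and sinusoidal endothelium (-0.12) lists had downward camera calls, the first 3 against positive medians, at adjusted p of 0.000501, 0.0196, 0.0356, 0.000163 and 0.000307. Those 5 calls were lost, the lowest at adjusted p = 0.350 with an estimated correlation, and the bile acid, gluconeogenesis and hepatocyte medians turned negative under median-of-ratios scaling (-0.30, -0.13 and -0.29). Leaving out each S302A_Ctrl and S302A_DEN replicate in turn put these medians between -0.16 and 0.10 (bile acid), -0.15 and 0.17 (gluconeogenesis), -0.06 and 0.11 (hepatocyte), -0.38 and -0.09 (male-biased) and -0.40 and 0.08 (sinusoidal endothelium). The male-biased, gluconeogenesis and hepatocyte calls ended without S302A_DEN replicate 3 (adjusted p = 0.124, 0.884 and 0.221), and the hepatocyte call also without S302A_Ctrl replicate 1 (0.0889). Tumour and fetal liver genes were higher in 11 of 12 (median 1.12, camera adjusted p = 0.122) and macrophage genes in 14 of 14 (median 0.59, adjusted p = 0.699), neither past the test, and both stood highest in S302A_DEN replicate 3.

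**Figure D3:**
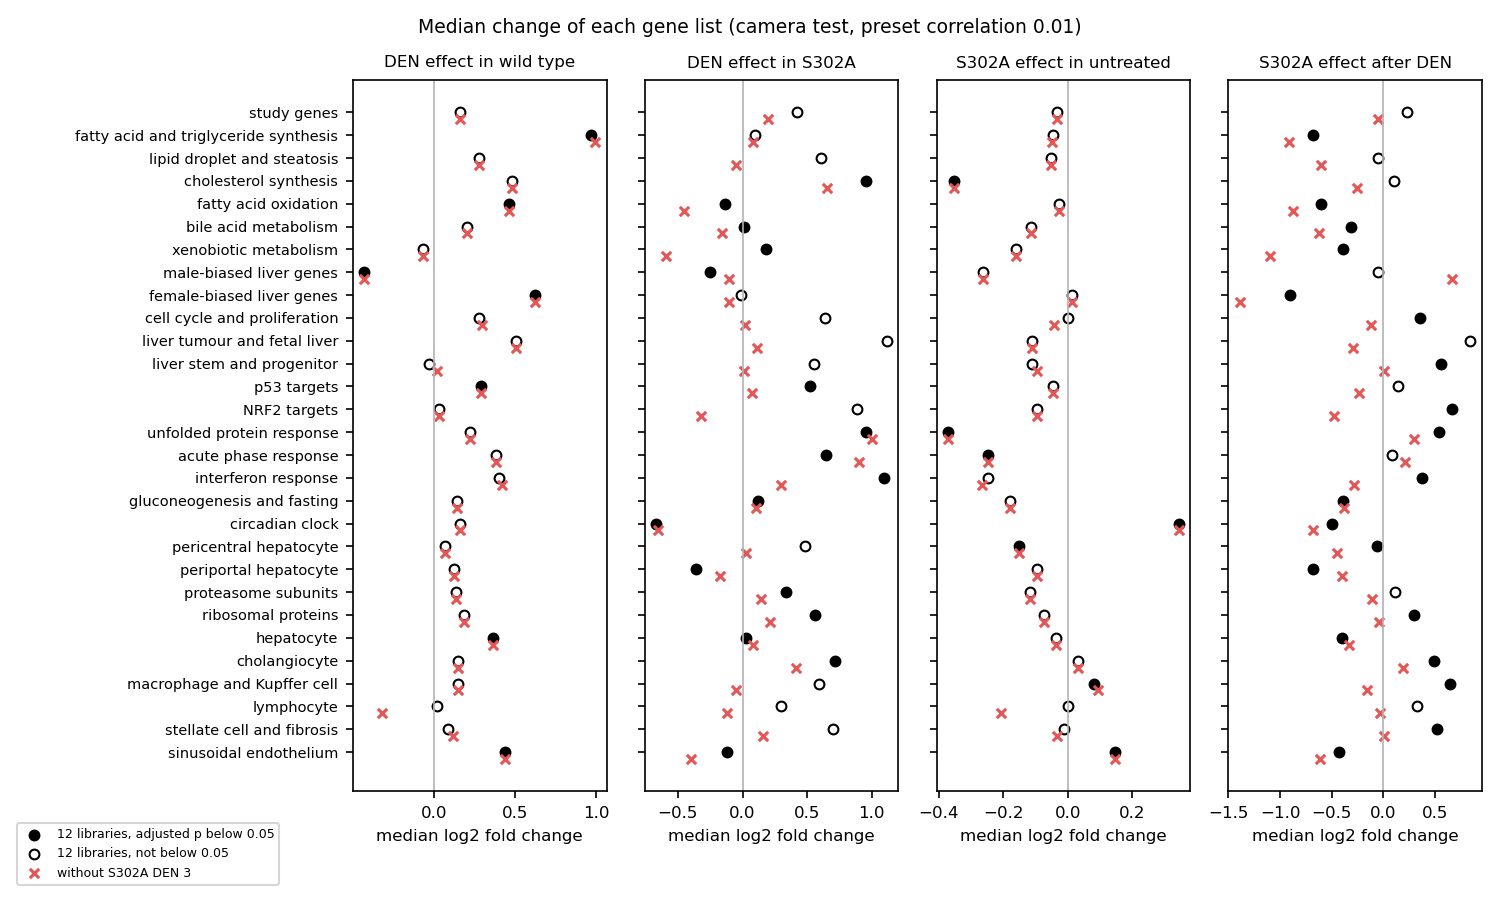
Median log2 change of each gene list in the 4 pairwise comparisons; filled points mark camera adjusted p below 0.05 with the preset correlation, none of which held with an estimated correlation, and crosses give the median without S302A_DEN replicate 3. The fatty acid and triglyceride synthesis list lies at 0.97 for DEN in wild type and at -0.68 for S302A after DEN.

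The untreated comparison, S302A_Ctrl with WT_Ctrl, asked what the allele changed without carcinogen. Rpph1 rose from 1.40 ± 0.657 to 17.0 ± 8.86 TPM (SD, n = 3), with a log2 change of 2.81 ± 0.34 (SE; adjusted p = 0.0184). The other 3 genes past the test were transcript entries named here after their values were seen. AK200837 rose by 1.36, while AB343393 and AB343394 fell by 2.15, standing at 12.8, 4.85 and 7.69 TPM in WT_Ctrl and at 1 in S302A_Ctrl. Cyp2c37, an arachidonic acid-metabolising cytochrome P450 on chromosome 19 (39992424 to 40012243, plus strand), averaged 357 ± 101 TPM in WT_Ctrl and 62.1 ± 27.0 in S302A_Ctrl (-2.54, adjusted p = 0.113), short of the threshold. In total 4 genes passed, 2 up and 2 down, and 179 had an unadjusted p below 0.05. The 2 down, AB343393 and AB343394, held equal values in all 12 libraries and may be 1 transcript counted under a pair of entries. The count was 0 without WT_Ctrl replicate 1, WT_DEN replicate 2, WT_DEN replicate 3 or S302A_Ctrl replicate 2, 1 without S302A_Ctrl replicate 1, 2 without WT_Ctrl replicate 2 or S302A_Ctrl replicate 3 and 12 without WT_Ctrl replicate 3. The Rpph1 call ended without WT_Ctrl replicates 1 and 2, WT_DEN replicates 2 and 3 and S302A_Ctrl replicates 1 and 2 (adjusted p from 0.0563 to 0.0997). It also ended without a filter (0.0665), where limma called 0 genes and 211 had an unadjusted p below 0.05, and with the 6 libraries of this contrast alone (0.0732), where 2 other genes passed.

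Among gene groups in untreated livers, 7 of 29 lists passed camera. Of the 10 splits of these libraries, the real one included, 6 gave at least 7 lists (highest other 12). The number of lists therefore does not set the genotype apart from a regrouping of the samples. Cholesterol synthesis genes were lower in the knock-in in 23 of 24 (median -0.35, camera adjusted p = 0.000290), lost at adjusted p = 0.969 with an estimated correlation and without WT_Ctrl replicate 1 (0.397), S302A_Ctrl replicate 1 (0.0787) or S302A_Ctrl replicate 3 (0.0599). Of them 0 passed over all genes and 0 adjusted over the list alone. The cholesterol median was -0.09 and -0.66 without WT_Ctrl replicates 1 and 3, and -0.65 and -0.19 without S302A_Ctrl replicates 2 and 3. Genes of the unfolded protein response were lower in 13 of 18 (median -0.37, camera adjusted p = 0.0149), lost at adjusted p = 0.969 with an estimated correlation, without WT_Ctrl replicate 2 (0.356), S302A_Ctrl replicate 1 (0.370), S302A_Ctrl replicate 3 (0.0599) or S302A_DEN replicate 3 (0.269), and under median-of-ratios scaling (0.0736). Clock genes were higher in 13 of 18 (median 0.34, camera adjusted p = 0.000304), lost at adjusted p = 0.814 with an estimated correlation, at 0.0787 without S302A_Ctrl replicate 1 and at 0.0577 under median-of-ratios scaling. Their median was 0.02 without WT_Ctrl replicate 2, 0.55 without S302A_Ctrl replicate 2 and 0.20 without S302A_Ctrl replicate 3. Pericentral hepatocyte genes were lower in 13 of 16 (median -0.15, mean -0.40, camera adjusted p = 0.000290), lost at adjusted p = 0.814 with an estimated correlation. No pericentral gene passed over all genes and 2 fell adjusted over the list alone; the median was -0.09 without WT_Ctrl replicate 1 and -0.25 and -0.24 without WT_Ctrl replicate 2 and S302A_Ctrl replicate 2. Acute phase genes were lower in 21 of 26 (median -0.25, camera adjusted p = 0.00427), lost at adjusted p = 0.814 with an estimated correlation, without WT_Ctrl replicate 2 (0.350) or S302A_Ctrl replicate 1 (0.132) and under median-of-ratios scaling (0.0736). Sinusoidal endothelial genes were higher in 13 of 13 (median 0.15, camera adjusted p = 0.000467), lost at adjusted p = 0.969 with an estimated correlation, at 0.729 without WT_Ctrl replicate 1 and at 0.564 with a median of -0.04 without S302A_Ctrl replicate 1. Macrophage genes were higher in 8 of 14 (median 0.08, camera adjusted p = 0.0462), lost at adjusted p = 0.969 with an estimated correlation, without WT_Ctrl replicate 1 (0.955, median -0.02), WT_Ctrl replicate 2 (0.356), S302A_Ctrl replicate 3 (0.972) or S302A_DEN replicate 3 (0.0590), and under median-of-ratios scaling (0.380).

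The genotype comparison after DEN, S302A_DEN with WT_DEN, asked whether the allele altered the carcinogen-treated liver. Cyp2b10, a drug-metabolising cytochrome P450 on chromosome 7 (25897620 to 25926624, plus strand), fell from 12.7 ± 2.20 to 1.44 ± 0.769 TPM (SD, n = 3), with a log2 change of -2.51 ± 0.27 (SE; adjusted p = 0.00285). Cyp2c37 fell from 322 ± 77.3 to 43.1 ± 28.3 TPM (-3.04 ± 0.42, adjusted p = 0.0118) and its neighbour Cyp2c54 from 347 ± 16.7 to 62.0 ± 35.1 TPM (-2.61, adjusted p = 0.00747). Cyp2c50 and Cyp2c29 fell from 839 ± 187 to 183 ± 90.8 TPM and from 1712 ± 351 to 395 ± 162 TPM; the Cyp2c genes are near-identical, so the division of reads among them is uncertain. Cyp4a10, a fatty acid omega-hydroxylase, fell from 138 ± 47.2 to 15.8 ± 22.3 TPM (-3.97, adjusted p = 0.0477). Fitm1, a lipid droplet assembly gene, fell from 47.7 ± 9.12 to 11.4 ± 6.20 TPM (-2.06, adjusted p = 0.0390). Gvin1, an interferon-inducible GTPase gene, rose from 1.36 ± 0.475 to 6.40 ± 0.448 TPM (1.66, adjusted p = 0.00285). Spp1 rose from 20.8 ± 4.63 to 78.8 ± 37.6 TPM (1.80, adjusted p = 0.0390), and Fkbp11, a secretory-pathway prolyl isomerase, rose from 13.6 ± 2.60 to 54.1 ± 27.8. In total 46 genes passed, 13 up and 33 down, and 949 had an unadjusted p below 0.05. Under median-of-ratios scaling 65 were up and 145 down. The count was 700 (70 up, 630 down, 45 of the 46 included) without S302A_DEN replicate 3, and 19, 24, 12, 6, 20, 19 and 19 without WT_Ctrl replicate 3, WT_DEN replicates 1, 2 and 3, S302A_Ctrl replicates 1 and 3 and S302A_DEN replicate 2. Directions were 5 up and 1 down without WT_DEN replicate 3, and 10 up and 9 down without S302A_DEN replicate 2. Each other left-out library gave more genes down than up. Cyp2b10 and Gvin1 passed under each left-out library. With the 6 libraries of this contrast alone 4 of the 46 genes passed, and the calls of Cyp2b10 (adjusted p = 0.0524), Gvin1 (0.0976), Cyp2c37 and Cyp2c54 (0.0730 each), Cyp2c50 and Cyp2c29 (0.0897 each), Fitm1 (0.152), Spp1 (0.195), Fkbp11 and Cyp4a10 (0.214 each) ended. The Cyp2c37 and Cyp2c54 calls ended without WT_DEN replicate 3 (adjusted p = 0.0687 and 0.05002) and those of Cyp2c50 and Cyp2c29 without any WT_DEN replicate (0.0620 to 0.0863). The Cyp4a10, Fitm1, Spp1 and Fkbp11 calls each ended without 8 or more of the 11 libraries other than S302A_DEN replicate 3, at adjusted p from 0.0516 to 0.205. They also ended without a filter (0.113, 0.0802, 0.0766 and 0.0666), and the Cyp4a10 call with robust moderation (0.0853). Of 23 alternative settings, the Cyp4a10, Fitm1, Spp1 and Fkbp11 calls held in 8, 12, 11 and 13.

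After DEN, fatty acid and triglyceride synthesis was lower in the knock-in in 21 of 21 genes (median -0.68, camera adjusted p = 3.40e-12), lost at adjusted p = 0.209 with an estimated correlation; 0 passed over all genes and 7 fell adjusted over the list alone. Dgat2 averaged 261 ± 30.9 TPM in WT_DEN and 144 ± 14.4 in S302A_DEN (SD, n = 3; adjusted p = 0.0705). Fatty acid oxidation was lower in 18 of 20 (median -0.61, mean -0.97, camera adjusted p = 5.59e-15), lost at adjusted p = 0.209 with an estimated correlation; 2 fell over all genes and 12 adjusted over the list alone. Leaving out S302A_DEN replicate 3 made these counts 15 and 20, and fatty acid oxidation then passed at adjusted p = 0.0483 with an estimated correlation, as did xenobiotic metabolism. Cholesterol synthesis genes were higher in 14 of 24 without passing (median 0.10, camera adjusted p = 0.721), and their median was -0.01 without WT_DEN replicate 3 and -0.25 without S302A_DEN replicate 3. Lipid droplet genes were lower in 8 of 16 without passing (median -0.05, -0.60 without S302A_DEN replicate 3; camera adjusted p = 0.102). Xenobiotic metabolism genes were lower in 14 of 23 (median -0.39, camera adjusted p = 1.25e-05), lost at adjusted p = 0.276 with an estimated correlation in all libraries; Cyp2b10, Cyp2c29 and Cyp2c37 fell over all genes and 5 adjusted over the list alone. The xenobiotic median was 0.05 without S302A_DEN replicate 1 or replicate 2, -1.10 without replicate 3, and -0.23 and -0.17 without WT_DEN replicates 1 and 3. Female-biased genes were lower in 12 of 15 (median -0.91, -1.39 without S302A_DEN replicate 3; camera adjusted p = 1.10e-06), lost at adjusted p = 0.209 with an estimated correlation; Cyp4a10 and Acot3 fell over all genes and 6 adjusted over the list alone. Cyp4a10 is also in the fatty acid oxidation list, so the results of these lists are not fully separate. The Acot3 call ended without WT_DEN replicates 2 and 3 and S302A_DEN replicate 2 (0.0807, 0.110 and 0.0705) and with the libraries of this contrast alone (0.154). Bile acid genes were lower in 15 of 19 (median -0.31, -0.01 and -0.63 without S302A_DEN replicates 2 and 3; camera adjusted p = 2.31e-05), lost at adjusted p = 0.209 with an estimated correlation; 0 passed over all genes and 4 fell adjusted over the list alone. Sinusoidal endothelium was lower in 12 of 13 (median -0.43, -0.17 without S302A_DEN replicate 2; camera adjusted p = 7.10e-05), lost at adjusted p = 0.444 with an estimated correlation. The unfolded protein response was higher in 17 of 18 (median 0.54, 0.30 without S302A_DEN replicate 3; camera adjusted p = 9.78e-05), lost at adjusted p = 0.276 with an estimated correlation. Hepatocyte (median -0.40), periportal (-0.68), clock (-0.50) and gluconeogenesis (-0.39) genes were lower at camera adjusted p of 1.37e-06, 6.21e-06, 0.00315 and 0.00107; these were lost, the lowest at adjusted p = 0.209 with an estimated correlation, and without S302A_DEN replicate 3 (0.694, 0.381, 0.694 and 0.740).

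S302A_DEN replicate 3 moved with several lists that were higher in the knock-in after DEN. The cell cycle list (16 of 17 higher, median 0.36, camera adjusted p = 0.0368), NRF2 targets (15 of 16, 0.66, 0.0388), interferon response (20 of 21, 0.38, 0.0282) and macrophage genes (13 of 14, 0.64, 0.00841) passed camera, each lost at adjusted p = 0.661 with an estimated correlation. Without that library their medians were -0.12, -0.47, -0.28 and -0.16, and without S302A_DEN replicate 2 they were 0.58, 1.41, 0.91 and 1.21. The interferon call also ended without WT_DEN replicates 2 and 3 (0.0542 and 0.144), the macrophage call without WT_DEN replicate 2 (0.0542) and S302A_DEN replicate 1 (0.0531), and the NRF2 call without WT_Ctrl replicate 1 (0.0537) and WT_DEN replicate 1 (0.0589) and under median-of-ratios scaling (0.0565). The cell cycle call ended without WT_DEN replicates 1 and 2, S302A_Ctrl replicate 1 and S302A_DEN replicate 2 (0.190, 0.0542, 0.0597 and 0.0732). Stem and progenitor (median 0.55, camera adjusted p = 0.00701), stellate cell and fibrosis (0.52, 0.00768), ribosomal protein (0.29, 3.34e-06) and cholangiocyte genes (0.48, 0.00770) were higher, lost at adjusted p of 0.524, 0.661, 0.661 and 0.423 with an estimated correlation, and their medians were 0.01, 0.00, -0.04 and 0.19 without S302A_DEN replicate 3. Pericentral hepatocyte genes were lower (median -0.06, camera adjusted p = 0.0279), lost at adjusted p = 0.639 with an estimated correlation, at 0.186 under median-of-ratios scaling and without WT_DEN replicate 3 (0.0561), S302A_DEN replicate 1 (0.0940) or S302A_DEN replicate 3 (0.258). These made 20 of 29 lists. Of the 10 splits of these libraries only the real one gave as many (highest other 18), and 10 splits are too few for a share below 0.05. Male-biased genes did not pass (median -0.05, mean 0.22, camera direction down, adjusted p = 0.382), but without S302A_DEN replicate 3 were higher (median 0.66, camera adjusted p = 4.06e-10), lost at adjusted p = 0.0641 with an estimated correlation. The study genes list (median 0.22, camera adjusted p = 0.0746) and lymphocyte genes (0.32, 0.139) did not pass.

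The interaction tested whether the DEN effect differed between genotypes. Cyp2b10 averaged 6.40 ± 1.47 TPM in WT_Ctrl and 12.7 ± 2.20 in WT_DEN, but 7.73 ± 1.73 in S302A_Ctrl and 1.44 ± 0.769 in S302A_DEN (SD, n = 3). The difference of its log2 DEN effects was -2.75 ± 0.39 (SE; adjusted p = 0.0259). Gvin1 differed by 2.14 ± 0.25 (adjusted p = 0.00653), with 1.98 ± 0.197, 1.36 ± 0.475, 1.14 ± 0.137 and 6.40 ± 0.448 TPM in WT_Ctrl, WT_DEN, S302A_Ctrl and S302A_DEN. The other 3 of the 5 genes past the test, named here after their values were seen, were the transcript entries AB343393 and AB343394 (4.67 each, adjusted p = 0.000347) and AK220016 (-11.78, adjusted p = 0.0155), and 613 genes had an unadjusted p below 0.05. AB343393 and AB343394 held equal values in all 12 libraries and may be 1 transcript. Fatty acid and triglyceride synthesis had a more negative DEN effect in the knock-in in 20 of 21 genes (median -0.66, camera adjusted p = 6.72e-10), lost at adjusted p = 0.263 with an estimated correlation. Fatty acid oxidation did too (median -0.61, camera adjusted p = 1.50e-13), lost at adjusted p = 0.263 with an estimated correlation; 4 of its 20 genes passed adjusted over the list alone, and 7 over all genes and 18 adjusted over the list alone without S302A_DEN replicate 3. The unfolded protein response had a more positive DEN effect (median 0.77, camera adjusted p = 1.81e-05), lost at adjusted p = 0.263 with an estimated correlation. In all 19 of 29 lists passed camera, of which 12 passed without S302A_DEN replicate 3, where 1 other list passed. Of 100 splits of the samples, the real one included, 6 gave at least 19 lists. The median over all genes was 0.14, which median-of-ratios scaling brought to 0.03, with 4 up and 8 down in place of 3 and 2. The count was 75 without S302A_DEN replicate 3, 3 without WT_Ctrl replicate 1, 13 without WT_Ctrl replicate 3 and 2 without WT_DEN replicate 3 or S302A_Ctrl replicate 2. The Gvin1 call ended without WT_DEN replicate 3 (adjusted p = 0.0525) and S302A_Ctrl replicate 2 (0.0502), and the Cyp2b10 call without 8 libraries, namely WT_Ctrl replicates 1 and 2, WT_DEN replicates 1 to 3, S302A_Ctrl replicates 2 and 3 and S302A_DEN replicate 1 (0.0550 to 0.109). The Cyp2b10 call also ended without a filter (0.0520), under median-of-ratios scaling (0.0745), with quantile normalization (0.0781) and without the most abundant genes (0.0525), and the Gvin1 call with the filter at 5 TPM (0.05998). Medians of the synthesis list were -0.34 without WT_Ctrl replicate 3 and -0.39 without S302A_Ctrl replicate 2.

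The DEN effect averaged over both genotypes drew on all libraries. Apoa4 rose by 3.55 ± 0.27 on the log2 scale (SE; adjusted p = 6.40e-05) and Cdkn1a by 3.07 ± 0.23 (adjusted p = 6.40e-05). Nfil3 rose by 1.74, Epha2 by 1.46, Zbtb16 by 1.48 and Chka, a choline kinase gene of phospholipid synthesis, by 1.98. Hsd17b6, a steroid and retinol dehydrogenase gene, fell by 2.08 (adjusted p = 0.0104) and Dbp fell by 3.30 (0.0191). Each of these calls except Dbp held under each left-out library, and the Dbp call ended without S302A_Ctrl replicates 1 and 3 (0.0537 and 0.0531). In total 162 genes passed, 127 up and 35 down, and median-of-ratios scaling made this 322 up and 386 down while moving the median of all genes from 0.21 to -0.00181. The count was 1037 without S302A_DEN replicate 2, 659 without S302A_DEN replicate 3 and 17 to 71 without each of the other 10 libraries. Of the genes called in the single genotypes, 4 rose in both, namely Apoa4, Cdkn1a, Nfil3 and Zbtb16, against 0.0589 expected. Of the called genes 0 fell in both. Fisher's exact test for the rises gave p = 2.70e-07 (one-sided), but it assumes independent calls. The genotypes share no control library, yet both contrasts took the spread of each gene from 1 fit of all 12 libraries. That p-value can therefore be too small. Leaving out S302A_DEN replicate 3 made the overlap 12 up against 2.79 expected and 6 down against 0.351. The overlap was 1 without WT_DEN replicate 3. It was 2 without WT_Ctrl replicate 3, WT_DEN replicate 2 or S302A_Ctrl replicate 1 or 3, without a filter, and with the libraries of each contrast alone. Camera called 11 of 29 lists for the average, among them interferon response (21 of 21 higher, median 0.69, adjusted p = 0.00273), lost at adjusted p = 0.861 with an estimated correlation. Of 100 splits of the samples, the real one included, 76 gave at least 11 lists, so that number does not set DEN apart from a regrouping. Without S302A_DEN replicate 3, where 21 of 21 interferon genes stood above both other replicates, the median was 0.39 (camera adjusted p = 0.00660, and adjusted p = 0.660 with an estimated correlation).

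The genotype effect averaged over both treatments called 2 genes, Cyp2c37 (-2.79, adjusted p = 0.00668) and Cyp2c50 (-1.80, adjusted p = 0.0422), both lower in the knock-in, and 534 genes had an unadjusted p below 0.05. The Cyp2c37 call held under each left-out library but ended under median-of-ratios scaling (adjusted p = 0.0641), without a filter (0.0617) and with quantile normalization (0.0731). The Cyp2c50 call ended under these settings too (0.158, 0.105 and 0.159) and without the most abundant genes (0.0876). The Cyp2c50 call ended without 8 libraries, namely WT_Ctrl replicates 1 and 2, WT_DEN replicates 1 to 3, S302A_Ctrl replicates 1 and 3 and S302A_DEN replicate 1, at adjusted p from 0.0517 to 0.161. Celf1 was higher in the knock-in by 0.58 without passing over all genes (adjusted p = 0.436), and it was the 1 of 16 study genes to pass adjusted over the list alone. The study genes list passed camera (median 0.10, adjusted p = 0.0225), lost at adjusted p = 0.696 with an estimated correlation and at 0.0529 without WT_Ctrl replicate 1, and its median was -0.07 without S302A_DEN replicate 3. Xenobiotic metabolism genes were lower (median -0.25, camera adjusted p = 1.43e-06), lost at adjusted p = 0.249 with an estimated correlation; 1 passed over all genes and 6 adjusted over the list alone, and the median was -0.64 without S302A_DEN replicate 3 and -0.01 without S302A_DEN replicate 2. The count was 95 without S302A_DEN replicate 3, 10 without WT_Ctrl replicate 3, 4 without S302A_DEN replicate 1 and 6 without S302A_DEN replicate 2, and 1 without WT_Ctrl replicate 1 or 2, any WT_DEN replicate or S302A_Ctrl replicate 1.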

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

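The tests of S302A_DEN replicate 3, of the clock genes and of the structural RNA entries were chosen only after the results were seen, and the scaling and tumour tests of that library and the scaling test of the clock genes were revised after their first results; the split counts were planned.

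S302A_DEN replicate 3 differed from both other DEN-treated knock-in livers, with tumour and fetal liver genes 3.52 higher at the median (log2). Scaling is excluded as the whole cause, since the difference was still 2.68 after median-of-ratios scaling, against 0.136 between the other 2 libraries. The values argue against a lower share of hepatocytes with all other cell types raised alike. Macrophage genes stood 2.09 and sinusoidal endothelial genes 0.512 higher, a difference of 1.58 (permutation p = 0.000180). That permutation regrouped genes of 1 library, which are not independent, so its p-value measures no spread between samples. Other changes of the cell mix were not tested. Tumour tissue in the piece of liver cannot be told apart from other causes: the tumour list ranked at percentile 100 of 10000 random lists, but NRF2 targets stood 3.56 higher, so the rise was not specific to tumour genes. A mislabelled or outside sample stays open and was not tested, and no count that includes this library can be read as typical of its group.

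Clock genes differed between DEN and untreated livers, with morning-phase genes (4 genes, mean 1.36) and evening-phase genes (10 genes, mean -0.846) moving apart by 2.21 (exact p = 0.00300 over 1001 regroupings of genes, which are not independent). One scaling factor per library is excluded by that distance, since it would move all genes of a library alike. Different hours of collection may account for it, but cannot be told apart from a DEN effect because the labels give no hour. Each untreated liver's deviation from the other controls of its genotype was set against the average DEN effect fitted without that liver. Of the 6, WT_Ctrl replicate 2 deviated most toward DEN in its clock genes, with a slope of 0.670. Over called non-clock genes its slope was 0.260, and the other controls had -0.131 to 0.466. Those genes were called without the liver in question and differed between controls, so the non-clock slopes do not decide the question.

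The transcript entries AB343393 and AB343394 differed in DEN effect between the genotypes by 4.67 each, and AK220016 by -11.78, by the interaction test. The AB343393 and AB343394 values were equal in 12 of 12 libraries, which fits 1 transcript counted under a pair of entries. They stood above 1 in all WT_Ctrl and S302A_DEN libraries and at 1 in all S302A_Ctrl and WT_DEN libraries, while AK220016 stood at 203 to 557 TPM in S302A_Ctrl and WT_DEN, at 1 to 5.93 in S302A_DEN and at 1.90, 1 and 93.3 in WT_Ctrl. Rpph1 was higher in untreated knock-in livers, as were, without passing, Rmrp (27.3, 16.1 and 3.58 TPM; adjusted p = 0.126) and Vaultrc5 (5.73, 10.8 and 2.89; 0.113), both at 1 in WT_Ctrl and at 1 to 1.52 after DEN, while the 73 tested short RNA genes other than Rpph1 had a median change of 0.00132, at percentile 99.62 of random lists, with 37 higher. A difference in how much structural RNA the library preparation kept may contribute. It cannot be told apart from genotype, because the labels give no preparation batch. Members went both ways, but many stood at or near the floor of 1, which holds their median near 0.

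Cyp2b10 had a DEN effect that differed between genotypes by -2.75 in the interaction test. Gvin1 differed by 2.14 in the same test.

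Gene lists whose DEN effect differed between genotypes by camera had the interaction medians below, with those without S302A_DEN replicate 3 in brackets, and none passed with an estimated correlation. Lower in the knock-in were fatty acid and triglyceride synthesis at -0.66 (-0.83), fatty acid oxidation at -0.61 (-0.88), bile acid metabolism at -0.27 (-0.56), xenobiotic metabolism at -0.16 (-0.89), female-biased genes at -0.92 (-1.53) and sinusoidal endothelium at -0.61 (-0.84). Higher were cholesterol synthesis at 0.46 (0.18), stem and progenitor genes at 0.66 (0.31), unfolded protein response at 0.77 (0.66), acute phase at 0.30 (0.63), ribosomal proteins at 0.37 (0.037) and cholangiocytes at 0.43 (0.13). The other 7 of the 19 calls ended without that library. Of these, gluconeogenesis at -0.068 (-0.14, adjusted p = 0.880), circadian clock at -0.73 (-1.01, 0.0761), periportal hepatocytes at -0.62 (-0.33, 0.404) and hepatocytes at -0.43 (-0.34, 0.541) were lower. Interferon response at 0.70 (-0.059, 0.404), proteasome at 0.24 (0.0052, 0.0799) and stellate cells at 0.50 (-0.0018, 0.513) were higher. Male-biased genes, not among the 19, passed without it at a median of 1.09 (adjusted p = 2.65e-08).

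The interaction called 5 genes, and 3 of 100 splits of the samples, the real one included, gave as many. These splits exchanged genotypes within each treatment, so they test for no genotype effect at all. Whether the interaction itself arose by chance is not decided by that count. The 5 genes also include AB343393 and AB343394, whose values were equal in all libraries. The highest other split gave 15. That split exchanged WT_Ctrl replicate 3 with S302A_Ctrl replicate 2 and the genotypes of all DEN libraries. It points to a structure of the samples, of which the genotype difference after DEN, still whole in it, can be part, and the cause was not tested. For the 19 lists of the interaction 6 of 100 splits gave as many and the highest other gave 21, so chance is not excluded.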

How the results depend on the processing

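The repeat of the naming rule without S302A_DEN replicate 3 and the choice by hand of the mitochondrial symbols left out with the most abundant genes came after the data were seen. So did the gene-by-gene estimation of array weights, used because the planned estimation did not converge; all other settings were planned. Outside the leave-one-out settings 7257 of the values of named genes kept their direction and side of the threshold, 379 newly passed, 162 no longer passed and 58 moved. No named gene reversed, which means that no direction changed where either result passed. For lists 647 kept both, 13 newly passed, 129 no longer passed and 23 moved, 18 of them under median-of-ratios scaling. A library outside a pairwise contrast does not enter its group means and acts only through the pooled spread and the genes kept. For DEN in wild type, leaving out S302A_DEN replicate 3 gave 258 genes in place of 16. The median change was then 0.136, against 0.131. Other causes were not tested except where a setting tests fewer genes or samples.

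Counts outside 1.5 times the main count follow by setting. Without a filter, which tests 13995 genes, they were 3 (DEN in wild type), 35 (DEN in S302A), 0 (S302A untreated; 211 genes at an unadjusted p below 0.05), 28 (S302A after DEN), 86 (average DEN), 0 (average S302A) and 2 (overlap). The filter at 5 TPM gave 132 for DEN in S302A, and a pseudocount of 0.1 gave 5 for average S302A. Median-of-ratios scaling gave 651 (DEN in S302A), 210 (S302A after DEN), 12 (interaction) and 708 (average DEN), and 4, 3 and 11 lists for DEN in wild type, S302A untreated and the interaction. Quantile normalization gave 33, 680, 188, 10, 719 and 0 for DEN in wild type, DEN in S302A, S302A after DEN, interaction, average DEN and average S302A, with an overlap of 11. Array weights gave 2057, 1609, 1996, 508, 3176 and 362 in that order, with an overlap of 390. The libraries of the contrast alone gave 147 (DEN in wild type), 17 (DEN in S302A), 2 (S302A untreated), 4 (S302A after DEN) and an overlap of 2. For the interaction and averages this equals the fit of all libraries. Leaving out the most abundant genes gave 8 (DEN in wild type), 360 (DEN in S302A), 137 (S302A after DEN), 406 (average DEN) and 6 (average S302A). A replicate block gave 5 (DEN in wild type), 87 (average DEN), 6 (average S302A) and an overlap of 2. Whether the replicate numbers pair the samples is not settled. Residual correlations of same-numbered libraries were -0.187 to 0.282 and of others -0.230 to 0.255. They exceeded 0.1 in 5 of 18 same-numbered pairs and in 5 of 36 others. With an estimated correlation 0 lists passed in each of the 7 contrasts. The naming rule without S302A_DEN replicate 3 found 192, 224, 1, 568 and 60 eligible genes for DEN in wild type, DEN in S302A, S302A untreated, S302A after DEN and the interaction, against 7, 59, 1, 33 and 2.

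Leaving out each library in turn gave 1 to 258 genes for DEN in wild type, 16 to 335 for DEN in S302A, 0 to 12 for S302A untreated, 6 to 700 for S302A after DEN, 2 to 75 for the interaction, 17 to 1037 for average DEN, 1 to 95 for average S302A and 1 to 18 for the overlap. Lists past camera ranged over 5 to 10, 13 to 20, 2 to 8, 12 to 21, 13 to 20, 11 to 14 and 13 to 22 in the order of the contrasts. Where either result passed, list directions by camera reversed only when 1 library was left out. The medians then, with the range over all left-out libraries in brackets, follow. Without S302A_DEN replicate 3 they were, for male-biased genes, -0.10 (-0.38 to -0.091) for DEN in S302A, 0.66 (-0.44 to 0.66) after DEN, 1.09 (-0.0030 to 1.09) for the interaction and 0.17 (-0.21 to 0.17) for average S302A. For NRF2 targets they were -0.32 (-0.32 to 1.34) for DEN in S302A, -0.47 (-0.47 to 1.41) after DEN, -0.083 (-0.083 to 0.84) for average DEN and -0.26 (-0.26 to 0.77) for average S302A. For DEN in S302A gluconeogenesis was at 0.10 (-0.15 to 0.17) and hepatocytes at 0.08 (-0.059 to 0.11). Cell cycle was at -0.12 (-0.12 to 0.69) after DEN and -0.17 (-0.17 to 0.24) for average S302A, interferon at -0.28 (-0.28 to 0.91) after DEN and acute phase at 0.021 (-0.12 to 0.021) for average S302A. Macrophage genes in untreated livers were at -0.02 (-0.098 to 0.42) without WT_Ctrl replicate 1, and the acute phase interaction was 0.22 (0.22 to 0.63) without S302A_DEN replicate 2. Count models (DESeq2, edgeR) were not run because values are TPM, and the unknown depth leaves the counting error of low values unknown.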

Other observations

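The tests of neighbours of Celf1, of GU-rich messages and of sample splits were planned; the other values here were picked out after the data were seen.

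Haemoglobin genes were high in 1 untreated knock-in liver. Hba-a2, a haemoglobin alpha gene, stood at 5062 TPM in S302A_Ctrl replicate 1, against 1649 and 1684 in replicates 2 and 3 and 905, 1398 and 1545 in WT_Ctrl. Alas2, the erythroid haem synthesis enzyme, averaged 40.3 ± 20.2 TPM (SD, n = 3) in WT_Ctrl, 97.1 ± 15.1 in WT_DEN, 85.3 ± 5.86 in S302A_Ctrl and 59.9 ± 31.2 in S302A_DEN, with no difference past limma. The 4 measured erythroid genes had a median log2 change of 0.93 for S302A in untreated livers and of -1.17 for DEN in S302A, untested. The 3 measured neutrophil genes had medians of -0.41 and 0.60 in these contrasts, the 2 adipocyte genes 0.14 and 0.14, the exocrine pancreas gene Cela2a -0.28 and 0.27 and the muscle gene Mylpf -0.03 and 0.18. No symbol of the mitochondrial list occurred in the data, although mitochondrial transcripts were present under other symbols such as Atpase6 and Cytb.

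Other genes varied widely within groups or set one group apart without passing limma in all 12 libraries, although some passed without S302A_DEN replicate 3. Mup9, a major urinary protein gene, stood at 311, 17242 and 1265 TPM in WT_Ctrl and at 12193, 24645 and 660 in S302A_DEN, at 13253, 21859 and 944 in S302A_Ctrl and at 145 to 248 in WT_DEN. Moxd1, a monooxygenase-like gene, stood at 54.6 and 50.8 TPM in S302A_DEN replicates 1 and 2 and at 1.03 in replicate 3. It stood at 15.5 TPM in WT_Ctrl replicate 2 and at 1 in every other library. Fabp5, a fatty acid-binding protein gene, stood at 380, 193 and 25.8 TPM in S302A_DEN and averaged 32.3 ± 9.001 in WT_DEN (SD, n = 3). Pttg1, the securin gene of chromosome separation, averaged 44.7 ± 21.7 TPM in WT_Ctrl, 42.2 ± 30.8 in WT_DEN, 5.19 ± 0.274 in S302A_Ctrl and 15.5 ± 20.7 in S302A_DEN. Prrg1 and Abhd1 averaged 3.97 ± 5.14 and 3.18 ± 3.75 TPM in WT_Ctrl and 24.9 ± 5.99 and 19.8 ± 7.39 in S302A_Ctrl, with 26.3 ± 10.1 and 19.4 ± 1.07 in WT_DEN (adjusted p = 0.0844 and 0.0878 for DEN in wild type). Without S302A_DEN replicate 3 these became 0.0343 and 0.0258, and the genotype comparison after DEN passed for Moxd1 (adjusted p = 0.00636), Fabp5 (0.00228), Pttg1 (0.0446) and Mup9 (0.0353). The average genotype effect then passed for Fabp5 (0.0417) and Pttg1 (0.0339).

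One hypothesis was that DNA of another strain around the edited gene changes its neighbours. Of 135 genes within 20 Mb of Celf1, 3 (Cd59a, Cerkl and Slc1a2) had an unadjusted p below 0.01 for the average genotype effect, against 118 of 10664 elsewhere, a ratio of 2.01 (Fisher's exact p = 0.193). With 3 genes the hypothesis cannot be told apart from no effect.

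Another was that messages with the GU-rich element TGTTTGTTTGT in the 3 prime UTR, which CELF1 binds, shift with genotype. The 415 genes with it among 10324 differed from the rest by 0.000273 on the log2 scale. Of the regroupings of the samples, 98 of 100 gave as large a difference, and the largest other was 0.0215. Such a shift was not seen in these data.

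Splits of the samples were counted for each result. For the average DEN effect (162 genes) 1 of 100 splits, the real one, gave as many and the highest other gave 4. Chance is excluded at 0.05. Against no DEN effect in either genotype, it is excluded too for the overlap of DEN effects (4 genes, 1 of 100, highest other 2). Whether the 2 genotypes respond independently was not tested by these splits. Chance is not excluded for the average S302A effect (2 genes, 5 of 100, highest other 15), for its 18 lists (12 of 100, highest other 21) or for the 11 lists of the average DEN effect (76 of 100, highest other 19). The split of 15 genes for the average S302A effect exchanged WT_Ctrl replicate 3 with S302A_Ctrl replicate 2, gave several times the real count and points to a structure of the samples. Apart from sign and scale it is the same comparison as the split of 15 genes for the interaction, so it adds no separate evidence. WT_Ctrl replicate 3 had Spearman correlations of 0.966, 0.965 and 0.977 with S302A_Ctrl replicates 1 to 3. With WT_Ctrl replicates 1 and 2 they were 0.958 and 0.962. All DEN libraries kept their genotype in that split, so the genotype difference after DEN can be part of that structure, and the cause was not tested. With 3 libraries against 3 the 10 splits are too few for a share below 0.05. The real counts and highest others were 16 and 1 (1 split as large) for DEN in wild type, 75 and 2 (1) for DEN in S302A, 4 and 1 (1) for S302A untreated and 46 and 1 (1) for S302A after DEN. For lists they were 7 and 14 (8), 17 and 18 (3), 7 and 12 (6) and 20 and 18 (1).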
